A study of Homo sapiens with 8 samples.

How the data were processed

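Gene expression was measured with Clariom S arrays, which carry 1 summary probe set for most genes, in human aortic endothelial cells (HAOEC), primary cells from the wall of the aorta. The cells had been kept for 6 hours in culture supernatant of macrophages, per the labels' protocols. Those macrophages had been differentiated from blood monocytes over 6 days, either without addition, named M(con), or with hemoglobin:haptoglobin complexes at 0.1 mg/ml, named M(Hb). The endothelial cells, not the macrophages, were put on the arrays. The labels gave 4 arrays for each of the 2 groups, and each column of the value table carried the title of its array. All 8 arrays were used, and 0 columns of per-sample values were left aside.

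The deposited table held log2 signals that the authors had summarised per probe set. The scale was read from the values, which ran from 2.01 to 18.04 with 2 decimals, with array medians between 6.24 and 6.36. Transcriptome Analysis Console was the tool named in the submitters' processing notes. Its version, the normalization method and the background correction are not given in the sources used here. The values were used as deposited, with no further normalization, and a log2 difference of 1 stood for a 2-fold difference of signal. The table had no detection p-values, so no statement on background is made, and levels between about 2 and 5 lie near the floor of the scale. Signals near 17 lie near its top, where a further rise can be compressed.

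Of the 21448 probe sets, 17709 had 1 gene symbol in the platform annotation used here, 0 had several, and 3739 had no gene name there. The named probe sets covered 17687 symbols, of which 20 had more than 1 probe set. All 17709 were matched through their Entrez gene identifiers to a RefSeq gene table of the assembly GRCh38.p14, and 0 symbols differed. That table served for names alone, because the build behind the probe sets is not given in the sources used here. Genes of multigene families with near-identical members, such as histones, metallothionein 1, class I HLA and the paralogs of CCL3, are reported as uncertain, since their probes can share targets. Genes that could identify a donor's sex were kept out of every named result.

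The difference between the groups, M(Hb) minus M(con), was tested per named probe set with limma (version 3.58.1 in R 4.3.3; linear model with empirical Bayes moderation, two-sided) and adjusted with Benjamini-Hochberg over all 17709 probe sets at a threshold of 0.05. Fixed gene lists (30 pathway lists and 7 lists of markers of other cell types) were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per symbol, the one with the highest mean. Benjamini-Hochberg adjustment ran over the 37 lists. The lists named 656 different genes, of which 605 were measured, and the remaining ones were not analysed here. For each list the calls among its members were counted with adjustment over all genes and adjusted over the list alone.

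The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap. It added up to 4 members of smallest p from each list the text describes, and 21 genes named in any case. Examples named outside this rule are marked as chosen after their values were seen.

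The test was tried on simulated data with the real gene means. With a spread pooled over both groups it recovered 49% of genes shifted by 1 and 89% of those shifted by 2 on the log2 scale, with 7 calls among 17509 unshifted genes. With each group's own spread it recovered 69% and 88% of 100 genes each, with 28 calls among the unshifted genes. Those 28 were a larger share of all calls than the adjusted threshold allows. The real groups also differed in spread, so false calls in the real test may exceed that threshold too. The list test called 5 of 5 shifted lists and 0 of 19 unshifted ones. The simulated noise was independent between genes, so that result does not show how the list test behaves when genes are correlated. The number of arrays limits the precision of every value below.

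Alternatives covered a replicate block, renewed quantile normalization, centring of each array on its median, array weights, eBayes with trend and robust options, and inclusion of every probe set. They also covered removal of the lowest 25% or 50% of probe sets, other thresholds, and leaving out each array in turn. Lists were also tested with an estimated correlation, with fry, with the mean of a gene's probe sets and without members that several lists share. Leaving out M(con) 1 and M(con) 2 together, and the estimated correlation without M(con) 2, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.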

Results

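The data consisted of 8 arrays of HAOEC, with 4 arrays of cells kept in M(con) supernatant and 4 of cells kept in M(Hb) supernatant. Each array gave log2 signals for the same 21448 probe sets. The comparison of M(Hb) with M(con) asked how supernatant of macrophages differentiated with hemoglobin:haptoglobin alters endothelial transcription. Its background is the study of endothelial-to-mesenchymal transition, in which endothelial cells acquire features of connective tissue cells. Nothing in the labels says that the arrays of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

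Endothelial cells in M(Hb) supernatant had higher signals for interferon-inducible genes and for ATF4 targets and amino acid response genes than cells in M(con) supernatant, and lower signals for genes of cell division. CXCL9, a chemokine induced by interferon gamma, rose from 6.10 ± 1.32 to 16.86 ± 0.03 on the log2 scale (mean ± SD, n = 4 each), near the top of the scale. CHAC1, which degrades glutathione and is a target of the transcription factor ATF4, rose from 7.50 ± 0.94 to 13.61 ± 0.10. KIF20A, a kinesin needed for cytokinesis, fell from 9.74 ± 1.47 to 3.65 ± 0.63. The list of transcription factors of endothelial-to-mesenchymal transition did not pass, with ZEB2 higher by 0.65, ZEB1 lower by 0.45 and SNAI1 at 11.81 ± 0.45 in M(con) and 11.78 ± 0.14 in M(Hb). M(con) 2 lay close to M(Hb) in the interferon list (mean 11.52 against 12.04) and towards it in the ATF4 list (11.26 against 12.50). Both lists lost their calls with an estimated correlation (adjusted p = 0.418 and 0.247), as did mitosis (0.247).

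In all, 1743 of 17709 probe sets passed the limma test at the adjusted threshold, 772 of them higher and 971 lower in M(Hb). A difference of at least 2-fold was found for 352 of the higher and 520 of the lower ones. The groups did not overlap for 3209 probe sets (18.1%, against 2.86% by chance), among them 1711 of the called ones. When each array was centred on its median, the split turned to 1347 higher and 732 lower, or 64.8% higher against 44.3% in the values as deposited, because centring moved the median difference of all genes by 0.13. Directions of small changes are therefore relative to the authors' scaling. At least 1 group mean lay below 5, near the floor, for IRF8, TNC, HLA-DRA, KLF4, NLRC5, MRC1, FABP4, KIF20A, TTK, TOP2A, NDC80, CDK1, CENPF, RRM2 and H2BC14, so the sizes of their differences below are uncertain.

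**Figure D1:**
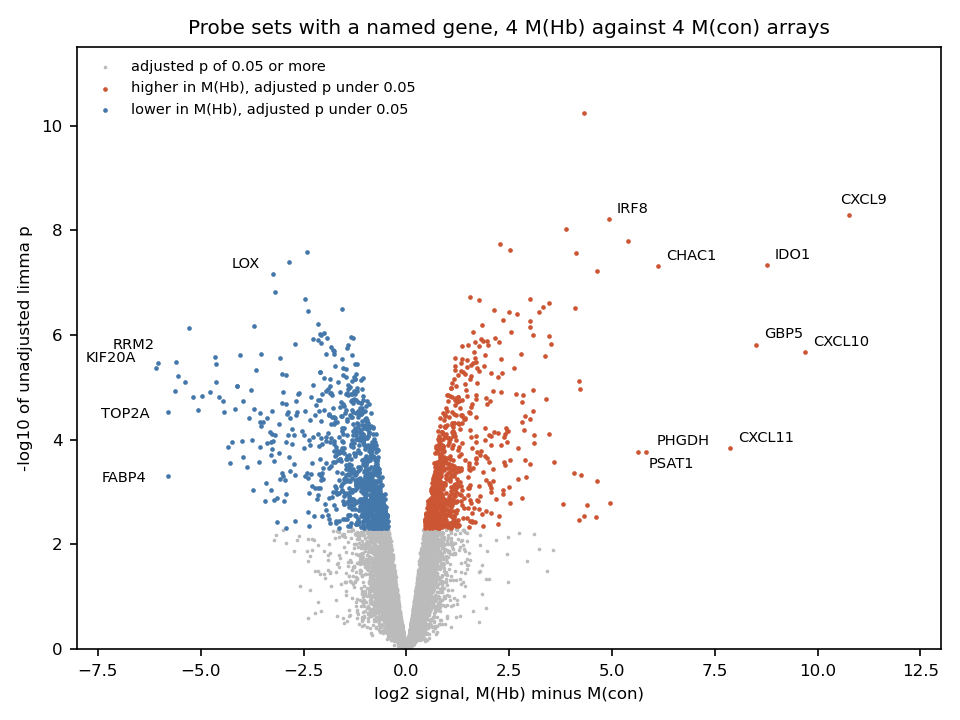
Each point is a probe set with a named gene (sex-linked genes that are not reported left out), with its log2 difference, M(Hb) minus M(con), on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis, from 4 arrays per group. Coloured points are the 772 higher and 971 lower probe sets past the adjusted threshold, with CXCL9 farthest to the right at 10.76.

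The arrays of the 2 groups differed in how closely they resembled each other. Pairs of M(Hb) arrays correlated across genes at 0.995 to 0.996, and pairs of M(con) arrays at 0.959 to 0.996. M(con) 2 stood apart, with correlations of 0.959 to 0.973 with the other M(con) arrays and of 0.964 to 0.965 with the M(Hb) arrays. Without M(con) 2, limma with Benjamini-Hochberg called 3158 genes, 1390 higher and 1768 lower, and 1738 of the 1743 genes called with all arrays were among them. Leaving out M(Hb) 2 gave the lowest count, 933 genes, 389 higher and 544 lower. With a replicate block in the fit, B2M, TNFAIP3, IER3, TAGLN, ZEB1 and ZEB2 lost their calls (adjusted p up to 0.125).

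Interferon-inducible genes made up many of the largest rises. Of 38 measured members of the interferon response list, 21 rose, 0 fell and 17 did not pass, and 29 rose when adjusted over the list alone. Their median difference was 2.46 (limma camera, adjusted p = 1.36e-17), and adjusted p = 0.418 with an estimated correlation. The chemokines CXCL9, CXCL10 and CXCL11 rose by 10.76, 9.69 and 7.88, and GBP2, a guanylate-binding protein, by 3.37. CXCL9 and CXCL10 reached 16.86 and 17.24 in M(Hb), near the top of the scale, so their rises may be understated. Outside the list, IDO1, the tryptophan-degrading enzyme, rose by 8.76 ± 0.56 (SE; limma, Benjamini-Hochberg adjusted p = 7.1e-05), GBP5 by 8.50 and the transcription factor IRF8 by 4.92. IFI44L and OAS1, which are also induced by type I interferons, rose by 4.96 and 4.63, and IFI44L kept its call only without M(con) 1 or M(con) 2 when 1 array was left out, with an adjusted p of up to 0.0753 in the 6 other fits. M(con) 2 had an interferon list mean of 11.52, close to the M(Hb) mean of 12.04 ± 0.19 and far above the other M(con) arrays at 7.83, 8.60 and 8.55. Without M(con) 2, 36 of the 38 members rose, with a median of 3.31.

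Genes for antigen presentation by class I molecules rose as well. Of 12 measured members, 7 rose and 5 did not pass, and 11 rose when adjusted over the list alone (median 1.08, limma camera adjusted p = 2.56e-07). The list had adjusted p = 0.412 with an estimated correlation. The peptide transporter subunits TAP1 and TAP2 rose by 3.07 and 2.46, and B2M, the light chain of class I molecules, rose by 0.73 from 16.43 to 17.16, where a rise can be compressed. B2M lost its call without M(con) 3, M(Hb) 1, M(Hb) 3 or M(Hb) 4, with an adjusted p of up to 0.0541. NLRC5, the transactivator of class I genes, rose by 1.05 but lay near the floor. The M(con) list means were 11.54, 13.15, 12.40 and 12.47 for replicates 1 to 4, and without M(con) 2 the number of rising members was 10.

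The list of ATF4 targets and amino acid response genes rose almost as a whole. Of 23 measured members, 21 rose, 0 fell and 2 did not pass, also when adjusted over the list alone, with a median of 2.12 (limma camera, adjusted p = 3.7e-21). It had adjusted p = 0.247 with an estimated correlation, and 0.0118 once M(con) 2 was left out, in a test added after the data had been seen. PHGDH, PSAT1 and PSPH, the enzymes of serine synthesis, rose by 5.84, 5.64 and 1.84. The mitochondrial folate enzyme ALDH1L2 rose by 4.12 and the secreted glycoprotein STC2 by 4.10. SLC6A9, a glycine transporter outside the list, rose by 5.38 ± 0.30 (SE; limma, Benjamini-Hochberg adjusted p = 5.41e-05). M(con) 2 had a list mean of 11.26, against 9.34, 9.18 and 9.11 in the other M(con) arrays and 12.50 ± 0.02 in M(Hb). Without M(con) 2, all 23 members rose.

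Genes of mitosis and DNA replication fell. In the mitosis list all 25 measured members fell, also when adjusted over the list alone, with a median of -3.97 (limma camera, adjusted p = 9.7e-27), and adjusted p = 0.247 with an estimated correlation. TTK and PLK1, kinases that control chromosome segregation, fell by 6.04 and 5.38, and TOP2A, which untangles DNA before division, by 5.80. CENPF, DLGAP5 and CDK1 fell by 5.18, 5.28 and 4.97, and ANLN and NDC80, division genes outside the list, by 5.56 and 5.07. Of 25 DNA replication genes, 0 rose, 19 fell and 6 did not pass, and 21 fell when adjusted over the list alone (median -1.44, limma camera adjusted p = 1.36e-17). That list too had adjusted p = 0.247 with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, fell by 5.61, TYMS, which makes thymidylate, by 3.53, and the helicase subunit MCM5 by 1.88. H2BC14, a replication-dependent histone whose probes may share targets with other histones, fell by 5.62. M(con) 1 had a mitosis list mean of 7.63, between the other M(con) arrays at 10.60, 10.01 and 10.10 and M(Hb) at 5.55 ± 0.04. Without M(con) 2, 25 mitosis and 22 replication genes fell.

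**Figure D2:**
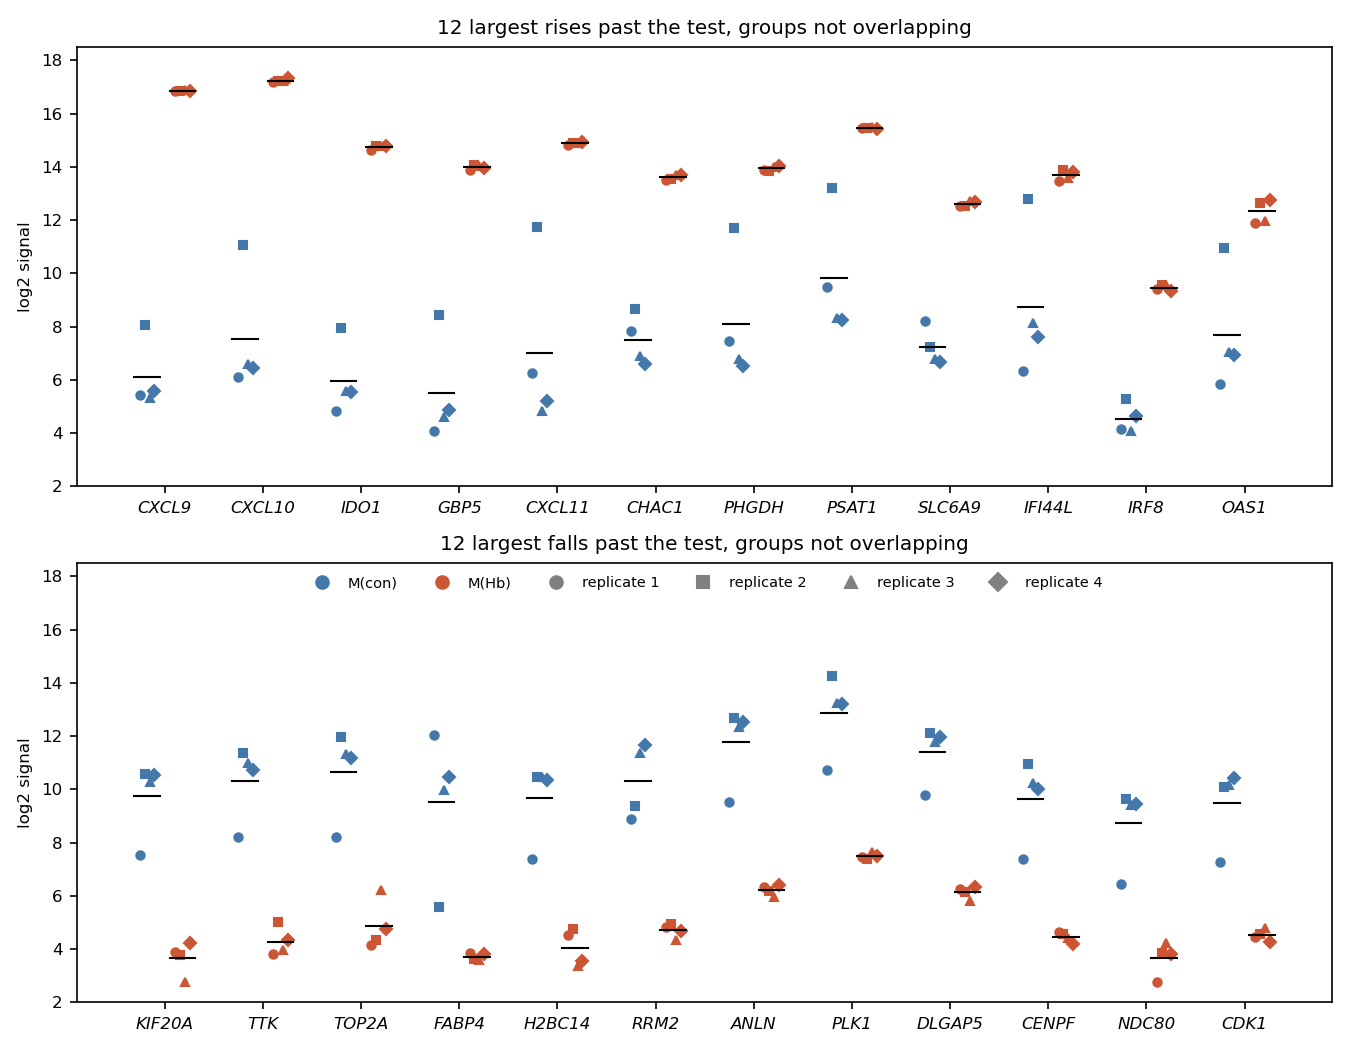
Log2 signal of the 12 largest rises (upper panel) and the 12 largest falls (lower panel) among genes past the test whose groups do not overlap, with 1 point per array, marker shape for the replicate and a line at each group's mean. M(con) 2 lies above the other M(con) arrays for CXCL10, at 11.07, and M(con) 1 lies below them for KIF20A, at 7.55.

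Sterol synthesis genes fell in part. Of 21 members measured, 0 rose, 7 fell and 14 did not pass, and 8 fell when adjusted over the list alone (median -0.69, limma camera adjusted p = 1.05e-06). The list had adjusted p = 0.412 with an estimated correlation. TMEM97, a regulator of cholesterol trafficking, fell by 3.26, INSIG1, which retains the sterol sensor in the endoplasmic reticulum, by 1.80, and the sterol enzymes CYP51A1 and SQLE by 1.58 and 1.57. List means in M(con) were 10.41, 9.29, 9.68 and 9.67 for replicates 1 to 4, against 8.82 ± 0.07 in M(Hb), and without M(con) 2 the number of falling members was 15. The median was -0.41 without M(con) 1 and -1.05 without M(con) 2. FABP4, a fatty acid carrier outside that list, fell by 5.79 ± 1.11 (SE; limma, Benjamini-Hochberg adjusted p = 0.0115), with M(con) 2 at 5.57 and the other M(con) arrays at 12.05, 9.96 and 10.47.

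Inflammatory activation genes rose in part. Of 35 measured members of the list of NF-kB targets and endothelial activation genes, 8 rose, 1 fell and 26 did not pass, and 13 rose and 1 fell when adjusted over the list alone. The median was 0.41 (limma camera, adjusted p = 0.00058), and adjusted p = 0.247 with an estimated correlation. IL1B rose by 2.18, and TNFAIP3 and IER3, which limit inflammatory signalling and cell death, by 0.71 and 0.62, with IER3 near the top of the scale in M(Hb) at 17.23. The call of IL1B was lost without any 1 of the M(Hb) arrays (adjusted p up to 0.0715), and TNFAIP3 and IER3 kept theirs only without M(con) 1 or M(con) 2 (up to 0.0836 and 0.0796 in the 6 other fits). SELE, the leukocyte adhesion molecule E-selectin, fell by 0.78 and lost its call without M(Hb) 4 at an adjusted p of 0.0521. ICAM1 and VCAM1 differed by 0.56 and -0.14 without passing, and ICAM1 passed once M(con) 2 was left out, at 0.71. CCL2 lay near the top of the scale in both groups, at 17.09 and 17.11, where a difference could not be read. M(con) list means were 12.99, 13.57, 13.37 and 13.40 for replicates 1 to 4, and without M(con) 2 the list had 14 rising and 3 falling members.

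Immediate early genes, which respond first to stimuli, had 4 risers and 1 faller among 23 measured, with 18 not passing and the same counts adjusted over the list alone (median 0.30, limma camera adjusted p = 0.0151). The list had adjusted p = 0.54 with an estimated correlation, and its call was lost without M(con) 1 (adjusted p = 0.0831), without members shared between lists (0.34) and with fry (0.0629). ATF3 rose by 2.92, MAFF by 0.92 and KLF4, near the floor, by 1.10, a call lost without M(Hb) 2, M(Hb) 3 or M(Hb) 4 (adjusted p up to 0.0562). M(con) 2 had a list mean of 9.42, above the M(Hb) mean of 9.23 ± 0.03, and the other M(con) arrays had 8.52, 8.70 and 8.70. Without M(con) 2, 10 members rose and 1 fell, with a median of 0.47, against 0.20 without M(con) 1.

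Genes of endothelial identity were measured to ask whether the cells kept their character. Of 25 members 1 rose, 5 fell and 19 did not pass, with 1 rising and 9 falling when adjusted over the list alone (median -0.32, limma camera adjusted p = 0.012). The list had adjusted p = 0.72 with an estimated correlation, and its call was lost without M(con) 1 (median -0.15, adjusted p = 0.19), without members shared between lists (0.0538) and with fry (0.12). VWF, the platelet-binding glycoprotein, fell by 1.82 ± 0.22 (SE; limma, Benjamini-Hochberg adjusted p = 0.00138), ICAM2 by 2.08, MMRN1 by 1.07 and ROBO4 by 0.94. CDH5, which encodes VE-cadherin, and NOS3 differed by 0.13 and 0.02 and did not pass, with NOS3 near the floor in both groups. PECAM1 and KDR differed by -0.51 and -0.53 without passing, and fell by 0.97 and 1.05 once M(con) 2 was left out. M(con) 2 had the lowest list mean of all arrays, below the 11.43 of M(Hb) 2, against 12.41, 12.01 and 12.07 in the other M(con) arrays and 11.44 ± 0.01 in M(Hb). Without it, 2 members rose and 12 fell.

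Coagulation and fibrinolysis genes shared part of these falls. Of 19 measured, 2 rose, 6 fell and 11 did not pass, and 2 rose and 7 fell when adjusted over the list alone (median -0.36, limma camera adjusted p = 0.00269), with adjusted p = 0.247 with an estimated correlation. Besides VWF and MMRN1, TFPI2, an inhibitor of tissue factor, fell by 1.47 and S100A10, which binds plasminogen at the cell surface, by 2.09. The M(con) list means were 11.70, 11.46, 11.30 and 11.41 for replicates 1 to 4, and without M(con) 2 the list had 2 rising and 8 falling members.

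The transcription factors of endothelial-to-mesenchymal transition did not shift as a list. Of 12 measured, 1 rose, 1 fell and 10 did not pass, and 2 rose and 2 fell when adjusted over the list alone (median 0.07, limma camera adjusted p = 0.86, adjusted p = 0.887 with an estimated correlation). ZEB2 rose by 0.65 and ZEB1 fell by 0.45, and when 1 array was left out ZEB2 kept its call only without M(con) 1 or M(con) 2 and ZEB1 only without M(con) 2, with adjusted p of up to 0.126 and 0.122 in the other fits. SNAI1, SNAI2 and TWIST1 differed by -0.03, 0.20 and -0.46 and did not pass, with adjusted p of 0.959, 0.582 and 0.0688 from limma with Benjamini-Hochberg. PRRX1 did not pass either, at 0.67 (adjusted p = 0.0503). TWIST1 and PRRX1 passed without M(con) 2, at -0.48 (adjusted p = 0.0449) and 0.735 (adjusted p = 0.0236). SNAI2 lay near the floor of the scale in both groups. The list had 2 rising and 3 falling members without M(con) 2, with a median of 0.11.

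Mesenchymal genes went both ways. Of 21 measured, 3 rose, 4 fell and 14 did not pass, and 3 rose and 5 fell when adjusted over the list alone. Leaving out M(con) 2 gave 3 rising and 7 falling members. The list did not pass (median -0.24, limma camera adjusted p = 0.0515, adjusted p = 0.412 with an estimated correlation), but it passed downward in 10 of 22 alternatives, among them those without M(con) 2 (adjusted p = 0.0215, and 0.179 with an estimated correlation on the same arrays), M(Hb) 2 (0.0323) or M(Hb) 4 (0.0462). Without M(con) 1 the median was -0.12 (adjusted p = 0.195). TNC, the matrix glycoprotein tenascin C, rose by 4.20 ± 0.48 (SE; limma, Benjamini-Hochberg adjusted p = 0.00102). TAGLN, an actin-binding protein of smooth muscle, rose by 1.52, close to the threshold at an adjusted p of 0.0486, and kept its call only without M(con) 1 or M(con) 2 when 1 array was left out, with an adjusted p of up to 0.131 otherwise. LOX, which crosslinks collagen, fell by 3.24, and the matrix proteins SPARC and POSTN fell by 1.53 and 1.23. ACTA2, VIM, FN1 and S100A4 differed by -0.07, -0.56, -0.24 and -0.54 without passing, and VIM, at a high 16.74 in M(con), passed without M(con) 2 at -0.40 (adjusted p = 0.0432).

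Genes of heme and iron handling fell in a few members. Of 20 measured, 1 rose, 3 fell and 16 did not pass, with 1 and 4 adjusted over the list alone (median -0.47, limma camera adjusted p = 0.0151, adjusted p = 0.247 with an estimated correlation). The call was lost without the lowest 25% of probe sets (adjusted p = 0.0774) and without members shared between lists (0.0538), and the median was -0.31 without M(con) 1. HMOX1, which degrades heme, fell from 11.80 ± 1.11 to 9.38 ± 0.14, with M(con) 2 highest at 13.28. SLC48A1, a heme transporter, fell by 1.67 and TFRC, the transferrin receptor, by 1.54. BACH1, a repressor of HMOX1, rose by 1.20 and lost its call without M(con) 3, M(Hb) 1, M(Hb) 2 or M(Hb) 4, with an adjusted p of up to 0.0609. The M(con) list means were 9.73, 9.92, 9.81 and 9.77 for replicates 1 to 4, and without M(con) 2 the list had 1 rising and 7 falling members.

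The metallothionein and zinc list had 2 risers and 0 fallers among 9 measured, with 7 not passing, and 3 risers when adjusted over the list alone (median 0.30, limma camera adjusted p = 0.00739). It had adjusted p = 0.565 with an estimated correlation. The risers were MTF1, the zinc-sensing transcription factor, by 1.35, and SLC30A1, a zinc exporter, by 1.47. The metallothioneins themselves, whose probes can share targets, did not pass, with MT1M at 0.57 and MT1F at 0.42, though both passed without M(con) 2, at 0.66 and 0.51 (adjusted p = 0.023 and 0.0359). List means in M(con) were 14.48, 15.07, 14.64 and 14.73 for replicates 1 to 4, and without M(con) 2 the number of risers was 5. The median was 0.12 without M(con) 1 (adjusted p = 0.0492) and 0.51 without M(con) 2.

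**Figure D3:**
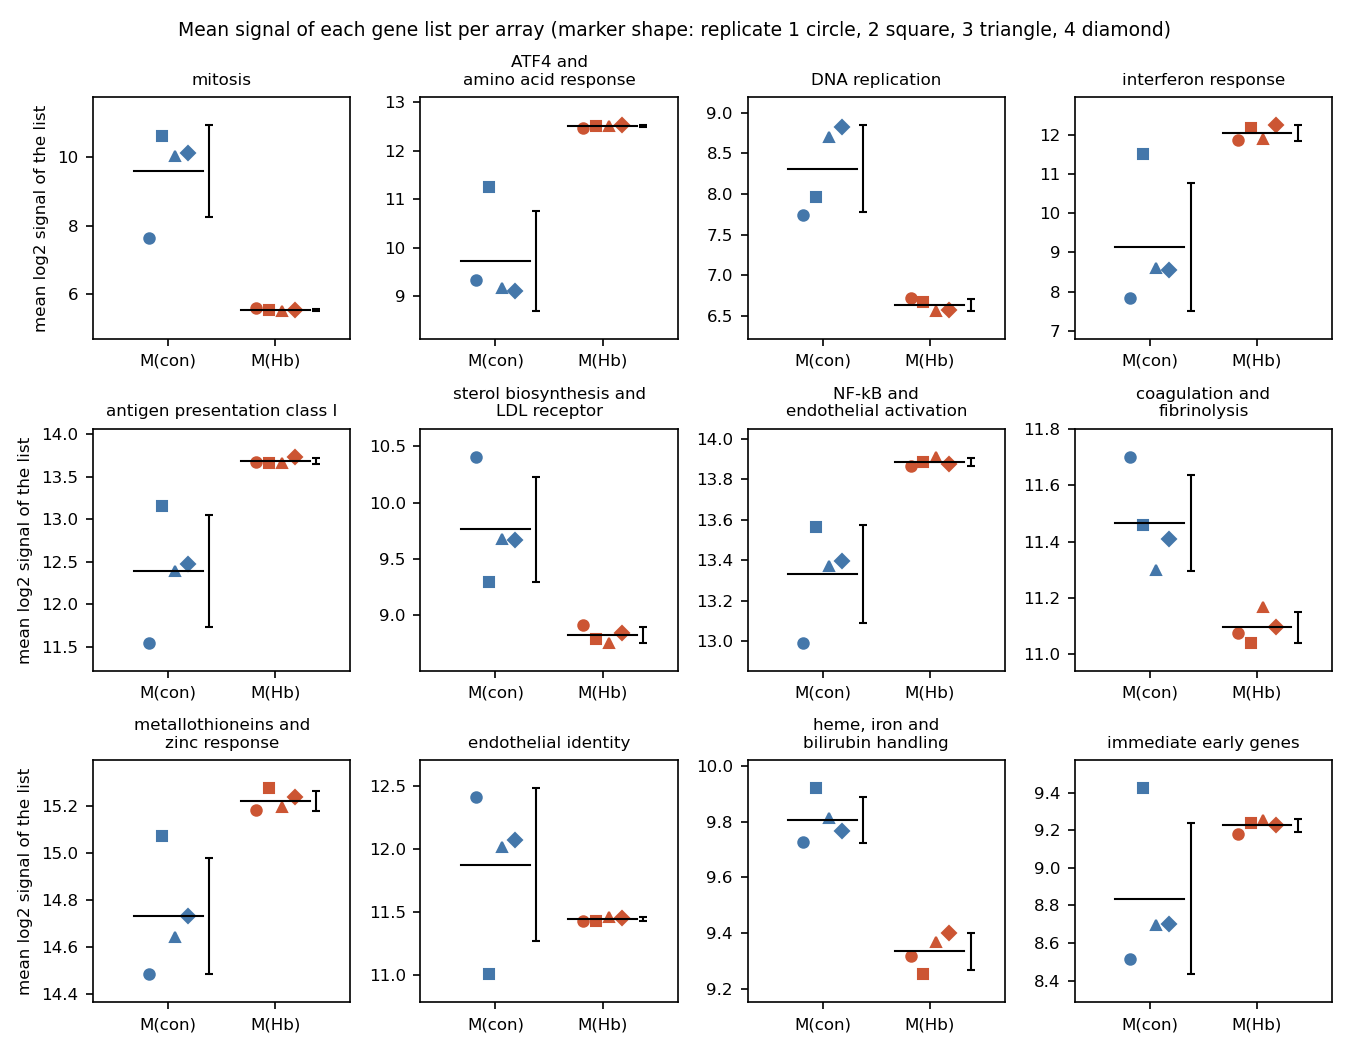
Mean log2 signal per array of the 12 lists that passed the list test, with 1 point per array, marker shape for the replicate, a line at the group mean and a bar of 1 SD each way over 4 arrays. The vertical axes differ between panels and do not start at 0. M(Hb) arrays have a smaller SD than M(con) arrays in every panel, while M(con) 1 and M(con) 2 lie apart from M(con) 3 and M(con) 4 in several, as at 7.63 for mitosis in M(con) 1 and 11.52 for interferon response in M(con) 2.

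Several other stress and signalling lists did not pass although single members changed. The hypoxia list had 6 risers and 3 fallers among 27 measured, 7 and 3 adjusted over the list alone (median 0.04, limma camera adjusted p = 0.476, adjusted p = 0.72 with an estimated correlation). VEGFA rose by 2.00, VLDLR by 3.48 and DDIT4, from 12.81 to 14.41, of which VLDLR and DDIT4 also belong to the ATF4 list, and VEGFA lost its call without M(Hb) 3 at an adjusted p of 0.0518. The NRF2 list had 2 risers and 4 fallers among 20, 4 and 4 adjusted over the list alone (median 0.33, mean 0.06, adjusted p = 0.575, adjusted p = 0.72 with an estimated correlation). SLC7A11, the cystine transporter, which also belongs to the ATF4 list, rose by 0.94. HMOX1, TKT and PIR fell by 2.42, 0.70 and 1.21, and PIR lost its call without M(Hb) 2 or M(Hb) 4 (adjusted p up to 0.0513). The unfolded protein response list had 3 of 16 members rising and 3 falling, 4 and 5 adjusted over the list alone (median -0.01, adjusted p = 0.765, adjusted p = 0.913 with an estimated correlation). Once M(con) 2 was left out, 3 of these members rose and 7 fell. HERPUD1 and DNAJB9 rose by 1.78 and 0.88, and the chaperones PDIA4 and CRELD2 fell by 1.06 and 1.30. PDIA4 kept its call only without M(con) 1, M(con) 2 or M(Hb) 1 when 1 array was left out, with an adjusted p of up to 0.0581 otherwise. Of 16 TGF-beta targets, 1 rose and 1 fell, 3 and 2 adjusted over the list alone (median -0.06 with camera pointing upward, adjusted p = 0.86, adjusted p = 0.913 with an estimated correlation). The counts of TGF-beta targets were 4 rising and 5 falling without M(con) 2. SMAD7, an inhibitor of that pathway, rose by 1.18, and TGFBI fell by 1.43 and kept its call only without M(con) 1 or M(con) 2 when 1 array was left out (adjusted p up to 0.076 otherwise).

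Markers of other cell types were measured as controls, and 0 of the 7 lists passed. Of 24 macrophage and monocyte markers, 2 rose and 1 fell, also when adjusted over the list alone (median 0.08, limma camera adjusted p = 0.628, adjusted p = 0.744 with an estimated correlation). The risers were CD74 and HLA-DRA, which interferon gamma also induces in endothelial cells, by 3.00 and 2.32, and MRC1 fell by 1.75. Among smooth muscle markers 1 of 13 rose, which was TAGLN, and 0 adjusted over the list alone (median 0.13, adjusted p = 0.739, adjusted p = 0.827 with an estimated correlation). Among 11 fibroblast markers 0 changed, with 0 adjusted over the list alone (median -0.10, adjusted p = 0.664, adjusted p = 0.787 with an estimated correlation), and M(con) 2 had their lowest mean at 4.47. The list of lymphatic endothelial markers had 1 faller of 9, MMRN1, also adjusted over the list alone (median 0.15, adjusted p = 0.86, adjusted p = 0.913 with an estimated correlation). Lymphocyte markers had 1 riser of 13, IL7R by 1.73, named after its value was seen, with 1 adjusted over the list alone (median 0.05, adjusted p = 0.435, adjusted p = 0.565 with an estimated correlation). Red cell and platelet markers had 0 changes among 13 (median 0.05, adjusted p = 0.635, adjusted p = 0.744 with an estimated correlation) and epithelial markers 0 among 11 (median 0.03 with a mean of -0.18, adjusted p = 0.737, adjusted p = 0.776 with an estimated correlation), both with 0 adjusted over the list alone.

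Of the 37 lists, 12 passed limma's camera with the preset correlation, 6 upward and 6 downward, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.247 and 7 lists had an unadjusted p under 0.05. With fry, which asks whether the members of a list move together and compares them with no other genes, 13 lists passed.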

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

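The tests of M(con) 2 (exchanged label, macrophage RNA, other cells), of macrophage RNA in the M(Hb) arrays and of the unfolded protein response, and the adjustment of splits over all 37 lists, were chosen after the results they concern had been seen. The counts over other splits of the arrays and the tests of scaling and of single M(con) arrays were set before. Bootstrap intervals below resampled the genes of a list, which are not independent, and hold no spread between arrays.

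In 276 groups of 4 arrays, of which 200 were of named genes, 74 of list means and the rest of each array's mean correlation with its group, 1 array lay far from 3 close ones in 26 groups, while chance gives about 5%. M(con) 2 accounted for 7 of these. It had CXCL9 at 8.07 (other M(con) arrays 5.31 to 5.60), CXCL10 at 11.07 (6.12 to 6.58), CD74 at 8.36 (6.26 to 6.53) and PDIA4 at 12.08 (12.97 to 13.03). Its list means were 10.07 for TGF-beta targets (10.69 to 10.75), 11.26 for ATF4 and amino acid response (9.11 to 9.34) and 4.47 for fibroblast markers (5.36 to 5.49).

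M(con) 1 accounted for 10, most of them in genes of cell division. It had CDK1 at 7.27 (10.09 to 10.42), NDC80 at 6.44 (9.41 to 9.63), DLGAP5 at 9.79 (11.77 to 12.12), ANLN at 9.54 (12.36 to 12.69) and KIF20A at 7.55 (10.29 to 10.57). H2BC14 was at 7.40 (10.37 to 10.47), PRRX1 at 11.40 (12.06 to 12.18) and SQLE at 10.84 (9.68 to 9.80). Its list means were 7.84 for BMP targets (7.68 to 7.70) and 12.70 for heat shock (12.34 to 12.36).

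The other 9 lay within M(Hb), where most gaps were small. M(Hb) 1 had IDO1 at 14.62 (14.77 in the 3 others) and NLRC5 at 5.49 (4.78 to 4.89). M(Hb) 2 had MT1F at 14.96 (14.64 to 14.66), SNAI2 at 4.82 (4.29 to 4.35) and INSIG1 at 8.71 (8.59 in the 3 others). M(Hb) 3 had ICAM1 at 16.46 (16.24 to 16.25). M(Hb) 4 had CXCL10 at 17.32 (17.20 to 17.22), SELE at 14.89 (14.94 to 14.95) and MCM7 at 10.28 (10.52 to 10.54). Among the 3739 probe sets with no gene name here, which entered no comparison, 191 passed limma with Benjamini-Hochberg when every probe set was tested, 96 higher and 95 lower in M(Hb).

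Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, called genes (1743, highest other split 0). A chance division of these 8 arrays is thus argued against for that count, though 1 of 35 is the smallest share possible. Before adjustment, 4163 genes had a limma p under 0.05 in the real split. The split of M(con) 1, 3 and 4 with M(Hb) 1 had 1919. A chance difference between cultures cannot be excluded, because the arrays of a group may be repeats of 1 culture. For the count of lists chance cannot be excluded: 5 of the 35 splits called at least 12 lists, and the highest other split called 15. The 4 other splits of this kind all exchange M(con) 2 for an M(Hb) array and called 15, 15, 13 and 12 lists, which points to a structure of the samples. Each called list was also taken alone, by the size of its median, with no adjustment over the lists, which the real split had picked. In that test the real split was largest for mitosis (1 split, 3.97 against 3.08 in the highest other). The same held for ATF4 and amino acid response (1, 2.12 against 2.07) and interferon response (1, 2.46 against 2.22). It held for DNA replication too (1, 1.44 against 1.17). The real split was also largest for class I antigen presentation (1, 1.08 against 0.89) and sterol synthesis (1, 0.69 against 0.67). So it was for NF-kB and endothelial activation (1, 0.41 against 0.29) and heme and iron handling (1, 0.47 against 0.34). The margins are narrow for the ATF4 and sterol lists, and 1 of 35 is the smallest share possible. A Benjamini-Hochberg adjustment over all 37 lists (lowest share 0.106) could hardly have passed and decides nothing. Because the real split had also picked these lists, the ranks cannot exclude chance for them. Nor can chance be excluded for coagulation (4 splits, 0.36 against 0.42) or metallothioneins and zinc (4, 0.30 against 0.39), where other splits were larger. The same holds for immediate early genes (4, 0.30 against 0.37) and endothelial identity (14, 0.32 against 0.46). The highest other split exchanged M(con) 2 for an M(Hb) array in the ATF4, interferon, sterol, class I, metallothionein, immediate early and endothelial identity lists.

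M(con) 2 stood apart, with 67 genes more than 3 on the log2 scale outside the range of the 7 other arrays, 44 above and 23 below, while the next array, M(con) 1, had 7. An exchange of labels with an M(Hb) array is argued against, because 0 M(Hb) arrays correlated better with the other M(con) arrays than with their own group. RNA from macrophages is argued against by the median of 22 of their markers (without CD74 and HLA-DRA, which interferon induces), at -0.13 against the other M(con) arrays (bootstrap 95% interval -0.23 to 0.26). Of abundant macrophage transcripts LYZ was at 3.23 (3.57 in the other M(con) arrays), CD14 at 4.82 (5.16) and TYROBP at 7.67 (7.38). LAPTM5 was at 13.11 (13.95, and 13.30 in M(Hb)), high in both groups, so its level says little on added macrophage RNA. Higher in M(con) 2 were FCER1G at 5.10 (3.98) and CD68, which endothelial cells also express, at 13.31 (10.44). CCL3L3, whose probes can share targets, was at 11.33 (4.36 to 5.32 in the 7 others). The mean of all 24 markers was 5.81, the highest of the 8 arrays. Endothelial cells of another lot, donor or culture state, or a sample from outside the series, could give such a count of 67 genes and stay open, because no label tells the cultures of the arrays apart.

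Interferon genes were higher in M(Hb), with M(con) 2 close behind. Array scaling as the cause is argued against by a median of at least 2.45 under quantile normalization and centring, and dependence on 1 M(con) array by a median of at least 1.97 with any 1 of them left out. RNA from macrophages in the M(Hb) arrays is argued against by the median of the 22 markers, at 0.0675 (bootstrap 95% interval -0.13 to 0.13). An interferon in the M(Hb) supernatant is a biological explanation that may apply and was not tested, as cytokine levels were not analysed here.

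Mitosis genes were lower and ATF4 genes higher in M(Hb). Scaling is argued against by a smaller median of 2.16 in size under quantile normalization and centring, and dependence on 1 M(con) array by 1.86. Whether an unfolded protein response could be the source of the ATF4 rise cannot be told apart, because the median of its genes, -0.00875 (bootstrap 95% interval -0.51 to 0.42), lies over members called in both directions. M(con) 1 lay towards M(Hb) in mitosis (7.63) and M(con) 2 in ATF4 genes (11.26), so the 2 lists did not move together across the M(con) arrays. Depletion of amino acids or of growth factors in the M(Hb) supernatant is a biological explanation that stays open and untested.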

How the results depend on the processing

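Leaving out M(con) 1 and M(con) 2 together, and the estimated correlation without M(con) 2, were chosen after the data had been seen. The 80 named genes called with all arrays kept their direction, though not all of them their call, under all alternatives that tested them, as did the 12 called lists, and the reversals below all concern results that were not called. Without the lowest 50% of probe sets, 8 of the 80 were not tested. Calls were lost by 22 of the 80 at an adjusted p of 0.01, by 12 with an unadjusted p and a 2-fold difference, and by 0 to 14 when 1 array was left out, most without M(Hb) 4. The replicate block ended those of B2M (adjusted p = 0.0545), TNFAIP3 (0.0533), IER3 (0.0753), TAGLN (0.0541), ZEB1 (0.125) and ZEB2 (0.0808). Quantile normalization ended those of IER3 (0.0686) and ZEB2 (0.0646), centring that of ZEB1 (0.118) and inclusion of every probe set that of TAGLN (0.0518). The cause of each was not tested. Signal over background could not be judged without detection p-values, so low levels limit what can be said of NOS3, SNAI2, KLF4 and NLRC5 and of the other genes with a group mean near the floor. The alternatives of trend and robust eBayes (1761 genes), quantile normalization (1743, 844 higher and 899 lower), and removal of the lowest 25% (1897) or 50% (1802) of probe sets stayed within 1.5 times the count of 1743.

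With a replicate block in the fit, 1192 genes passed, 486 higher and 706 lower, and the same 12 lists were called. The replicate numbers gave no clear sign of a pairing of the arrays, but a pairing is not excluded. Deviations of same-numbered arrays correlated at 0.0993, 0.0257, 0.0273 and -0.00864 across genes, with 0 of them over 0.1. Even so, 2 of 4 M(con) and 3 of 4 M(Hb) arrays correlated best with their own number.

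Counts of genes depended on the threshold and on the weight of M(con) 1 and M(con) 2. Centring on the median gave 1347 higher genes. Array weights gave 3993 genes, 1899 higher and 2094 lower, and leaving out M(con) 1 and M(con) 2 gave 3661, 1727 higher and 1934 lower. An adjusted p of 0.01 gave 706 genes, 300 higher and 406 lower, and one of 0.1 gave 2621, of which 1219 were higher. An unadjusted p of 0.05 with a 2-fold difference gave 1095 genes, 435 of them higher. Leaving out 1 array gave 933 to 3158 genes, 389 to 1390 higher and 544 to 1768 lower, the lowest without M(Hb) 2 and the highest without M(con) 2.

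Camera with an estimated correlation called 0 lists, 0 higher and 0 lower, and without M(con) 2 it called 1, with 1 higher and 0 lower. Leaving out 1 array gave 10 to 15 lists, 5 to 7 higher and 5 to 8 lower. Fry called 13 lists and did not call endothelial identity (adjusted p = 0.12) or immediate early genes (0.0629), while it called mesenchymal genes (0.00766), glucocorticoid response (0.00288) and extracellular matrix enzymes (0.00353). Removing members that several lists share left 10 lists, as it ended the calls of endothelial identity, heme handling and immediate early genes and added glucocorticoid response (median 0.495, adjusted p = 0.0272). Heme handling was also lost without the lowest 25% (adjusted p = 0.0774) or 50% (0.156) of probe sets, and endothelial identity and immediate early genes without M(con) 1.

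Values that changed sign were as follows. Renewed quantile normalization gave NOS3 -0.0078, ACTA2 0.023, CCL2 -0.11 and hypoxia targets -0.051. Centring gave ACTA2 0.060 and SNAI1 0.10, and list medians of 0.066 for TGF-beta, 0.12 for VEGF response, 0.11 for flow-responsive genes, 0.12 for the unfolded protein response, 0.12 for heat shock, 0.033 for p53, 0.094 for matrix enzymes and 0.025 for fibroblast markers. Without the lowest 25% of probe sets, heat shock was at 0.0375, complement at -0.21, red cell and platelet markers at -0.0075 and epithelial markers at -0.60. Without the lowest 50%, LXR targets were at -0.37, the unfolded protein response at 0.055, heat shock at 0.0375, complement at -0.085 and epithelial markers at -0.60. Array weights gave CDH5 -0.0497, CCL2 -0.00437, VEGF response 0.0836, LXR targets -0.0116, fatty acid oxidation -0.0295 and heat shock 0.10. Without shared members, hypoxia targets were at -0.0725 and matrix enzymes at 0.0125. Without M(con) 1 and M(con) 2, CDH5 was at -0.0525, CCL2 at -0.01, VEGF response at 0.0925, LXR targets at -0.0475, fatty acid oxidation at -0.0625 and heat shock at 0.12. The estimated correlation without M(con) 2 had flow-responsive genes at 0.0842, LXR targets at -0.0742 and fatty acid oxidation at -0.025.

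Leaving out 1 array moved SNAI1 between -0.24 and 0.0967, ACTA2 between -0.24 and 0.0567, CDH5 between -0.20 and 0.34, VCAM1 between -0.46 and 0.11 and NOS3 between -0.18 and 0.17. List medians ranged from -0.25 to 0.11 for TGF-beta, -0.00917 to 0.0975 for hypoxia, -0.0404 to 0.16 for VEGF response, -0.32 to 0.0375 for Notch, -0.33 to 0.11 for the unfolded protein response, -0.13 to 0.095 for heat shock, and -0.0879 to 0.0075 for matrix enzymes. They ranged from -0.00542 to 0.23 for complement, -0.14 to 0.0842 for flow-responsive genes, -0.0742 to 0.19 for LXR targets, -0.025 to 0.25 for fatty acid oxidation and -0.0192 to 0.055 for epithelial markers.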

Other observations

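The gene families, the synthetase test and the test of interferon genes in M(con) 2 were chosen after the results had been seen, as were the list members named as examples here. The lists themselves were among those set beforehand.

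Some gene families, which overlap the called lists in part, were counted without a test against other genes (limma with Benjamini-Hochberg over all genes for each member). All 7 measured guanylate-binding protein genes were higher, from 1.40 for GBP3 to 8.50 for GBP5, with a median of 3.09. Of 6 apolipoprotein L genes, which are also induced by interferons, 5 were higher (median 2.09). Among 61 replication-dependent histone genes, whose probes can share targets, 35 were lower and 0 higher (median -1.19).

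Vessel-type and matrix genes changed singly, and their lists did not pass limma's camera (adjusted over 37 lists). Notch and arterial genes had 1 riser and 3 fallers among 16, 2 and 4 adjusted over the list alone (median -0.14, adjusted p = 0.401, adjusted p = 0.54 with an estimated correlation). The ligands JAG1, DLL4 and EFNB2 fell by 2.54, 1.40 and 2.03, and the target HEY1 rose by 1.05. Extracellular matrix enzymes had 2 risers and 3 fallers among 16, 2 and 4 adjusted over the list alone (median -0.03, mean -0.67, adjusted p = 0.285, adjusted p = 0.439 with an estimated correlation), and MMP10 and ADAMTS1 fell by 2.92 and 2.93, while fry called the list (adjusted p = 0.00353). Junction genes had 1 riser and 2 fallers among 22, also adjusted over the list alone (median -0.24, adjusted p = 0.341, adjusted p = 0.744 with an estimated correlation). PLVAP, a component of endothelial fenestrae, rose by 1.36, and JAM2 and CAV1 fell by 1.39 and 0.74. The junction list passed downward without M(con) 2, with 2 risers, 7 fallers and a median of -0.43 (limma camera adjusted p = 0.0215, and 0.179 with an estimated correlation on the same arrays). Flow-responsive genes had 2 risers and 2 fallers among 16, 2 and 4 adjusted over the list alone (median -0.02, adjusted p = 0.677, adjusted p = 0.744 with an estimated correlation), with ASS1, which makes argininosuccinate, at 3.01. VEGF response genes had 2 risers and 1 faller among 24, also adjusted over the list alone (median -0.01 with camera pointing upward, adjusted p = 0.916, adjusted p = 0.922 with an estimated correlation), and NRP2 rose by 1.14. Leaving out M(con) 2 gave 5 risers and 6 fallers among the VEGF response genes. BMP targets had 2 risers and 0 fallers among 14, which were SMAD7 and HEY1, and 2 and 3 adjusted over the list alone (median 0.11, adjusted p = 0.785, adjusted p = 0.827 with an estimated correlation).

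Among metabolic and stress lists, complement genes had 2 risers and 0 fallers of 10, 4 and 2 adjusted over the list alone (median 0.18, limma camera adjusted p = 0.58, adjusted p = 0.725 with an estimated correlation). These were C1S and C1R, proteases of the first complement component, by 2.80 and 2.53. LXR targets and fatty acid synthesis genes had 1 riser and 3 fallers of 13, 4 and 5 adjusted over the list alone (median 0.11, mean -0.37 with camera pointing downward, adjusted p = 0.629, adjusted p = 0.725 with an estimated correlation). Leaving out M(con) 2 gave 4 risers and 6 fallers in that list. ELOVL6, PLTP and ACACA fell by 2.67, 2.31 and 0.93, and LPCAT3 rose by 1.10. Fatty acid oxidation and PPAR targets had 3 risers and 2 fallers of 15, 3 and 3 adjusted over the list alone (median 0.19, mean -0.16 with camera pointing upward, adjusted p = 0.629, adjusted p = 0.776 with an estimated correlation), with the lipid droplet protein PLIN2 higher by 1.51 and FABP4 the largest faller. Heat shock genes had 0 risers and 2 fallers of 11, 1 and 2 adjusted over the list alone (median -0.005, adjusted p = 0.579, adjusted p = 0.725 with an estimated correlation), which were the mitochondrial chaperones HSPD1 and HSPE1, by -1.27 and -1.46. The p53 targets had 1 riser and 1 faller of 15, PLK3 at 1.05 and SESN1 at -0.89, and 2 and 1 adjusted over the list alone (median -0.10, adjusted p = 0.697, adjusted p = 0.744 with an estimated correlation). Their counts were 3 rising and 5 falling without M(con) 2. Glucocorticoid response genes had 2 risers and 0 fallers of 13, TSC22D3 by 1.98 and CEBPD by 0.67, and 5 and 0 adjusted over the list alone (median 0.30, adjusted p = 0.0515, adjusted p = 0.247 with an estimated correlation), and the list passed upward in 10 of 22 alternatives, among them fry (adjusted p = 0.00288), while without M(con) 1 its median was 0.11 (adjusted p = 0.0958).

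The rise of ATF4 genes may extend to the cytosolic aminoacyl-tRNA synthetases, which are known ATF4 targets, and leave out the mitochondrial ones. Of 14 cytosolic synthetase genes 7 were higher and 0 lower (median 1.03), against 1 higher and 2 lower of 15 mitochondrial ones (median -0.27; two-sided Fisher's exact p = 0.0142 for higher calls, genes not being independent). CARS1 rose by 1.60 and IARS1 by 1.36. The families were read from the gene symbols alone, so a gene whose product serves both compartments would count as cytosolic. WARS1, at 2.15, is also induced by interferon gamma and counts among the 7.

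Whether M(con) 2 shares only part of the interferon response of the M(Hb) arrays stays open. Its position between the other M(con) arrays (0%) and M(Hb) (100%) averaged 133% over 9 IFIT, MX and OAS genes and 44.8% over 6 chemokine and guanylate-binding protein genes (exact permutation test over genes, two-sided p = 0.000999). That p cannot decide it, because the classes were picked after their values had been seen and genes of 1 array are not independent. CXCL9 and CXCL10 lie near the top of the scale in M(Hb), where compression would raise their positions, not lower them. The ranges also overlapped, from 76.0% for OAS1 to 276% for IFIT2 and from 15.2% for GBP2 to 84.5% for GBP4. The 23 other members ran from 47.8% for TAP1 to 509% for HERC5. HERC5 lay near the floor in the other M(con) arrays (3.22) and in M(Hb) (3.98), so its percentage is uncertain. The highest genes of M(con) 2 against all other arrays were SERPINB7 at 13.87 (3.51 to 4.44), SLCO2A1 at 12.20 (3.68 to 4.48) and NGFR at 12.04 (4.40 to 4.99). Among the lowest were RSPO3 at 4.35 (10.18 to 11.22), CD200 at 6.75 (12.03 to 12.68) and DCN at 6.44 (11.18 to 12.52).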
